A study of Homo sapiens with 24 samples.

How the data were processed

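RNA from AC16 cells was amplified, labelled and hybridized to Human Gene 2.0 ST arrays, 1 array for each of 24 samples in 8 groups of 3. Per the series' design text, the authors processed the arrays with GIANT, a suite of Galaxy tools, with Robust Multi-array Average normalization, which gives log2 values, and named limma for differential analysis. The versions and the background method are not given in the sources used here. The deposited log2 values covered 352859 probe sets per array, at the level of exons, and ran from 1.28 to 19.93. This range is wider than the log2 maximum of 16 of a 16-bit scanner, so an added transformation that is not stated is possible, and differences are reported on the deposited log2 scale and not as linear folds. The medians of the arrays ran from 6.25 to 6.38, a range of 0.13 that exceeded the limit of 0.1 set for further normalization.

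The labels are not uniform on the time of treatment. The growth protocol places collection 4, 16 and 20 h after treatment, while the labels of the T20 samples place it 4 h after treatment. All T16 samples are labelled untreated, so the protocol's hours cannot all count from digoxin or vehicle. The labels give replicate numbers but no day, batch or culture, so no pairing was used.

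Probe sets with exactly 1 gene symbol in the platform annotation were used (259224), and 13116 with several symbols and 80519 without a listing were left out. Older symbols were updated to current RefSeq symbols (1726), which left 22260 genes with a median of 10 probe sets. The probe set values were quantile normalized between arrays, and the probe sets of a gene were combined by median polish. Genes whose highest group mean was at or above the median of all gene values were tested, which left 11764. At or above a log2 value of 19.5, near the top of the scale, lay 719 probe sets on average, and 13 genes had 50% or more of their probe sets there. Genome positions were not used here.

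Differences between groups were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 24 arrays (16 residual degrees of freedom, 3.06 prior degrees of freedom), and p-values were adjusted by the method of Benjamini and Hochberg over the genes tested in each of 12 comparisons. A gene passed at an adjusted p under 0.05, two-sided. The comparisons were each dose of digoxin against the vehicle of the same time, the doses against each other, the effect at T20 minus the effect at T4 for each dose, and 4 comparisons between times. In T4 vehicle against T0 and in T20 vehicle against T16, time and vehicle change together.

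Fixed lists of genes (35) were tested against the other genes with camera and a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and fry run beside it. They held the circadian clock, the sodium potassium pump, calcium handling, immediate early genes, ATF4 targets, the unfolded protein response, heat shock, ubiquitin genes, proteasome subunits, p53 targets, G2 and mitosis, G1 to S, sterol synthesis and uptake, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrial biogenesis and fatty acid oxidation, the NRF2 response, metallothioneins and zinc, NF-kB targets, the interferon response, glucocorticoid targets, TGF-beta and matrix, apoptosis regulators, ribosomal proteins, ribosome biogenesis, histones, splicing factors, KRAB zinc finger genes, autophagy and lysosome, and markers of cardiomyocytes, fibroblasts, endothelium, smooth muscle and leukocytes. The lists, the comparisons, their tests and the rule for naming genes were chosen before the data were examined. By that rule the text names the 8 genes with the largest rise and the 8 with the largest fall among genes that passed and did not overlap between the groups in each digoxin comparison, 5 and 5 in each other comparison (by adjusted p alone for the difference between times), the clock and pump genes, and up to 4 members of a list with the smallest adjusted p. Symbols of unnamed loci (LOC and those with C and orf), of LINC genes, microRNAs, small nucleolar, Cajal body, small nuclear, 5S and 7S RNAs, olfactory receptors and antisense genes were passed over, and other non-coding genes and pseudogenes were not.

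Correlations of responses were taken across genes and set beside simulated unchanged groups. Unequal change among the probe sets of a gene was tested with diffSplice in limma, which was not among the comparisons planned. The workflow was tested on simulated data, in which 33.9% of genes changed by 0.5, 85.9% of those changed by 1 and 96.8% of those changed by 2 (log2) were recovered, with 5.1% false among 156 calls. Alternatives were other ways to combine probe sets, other filters on low values, other scalings, a replicate block, a fit of only the groups compared, eBayes with trend and robust, array weights, a minimum log2 change of 1 and each array left out in turn. Values as deposited, cyclic loess and centring on the 24 poly-A controls were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in python 3.11.15.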

Results

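AC16 cells are an immortalized line derived in part from adult human ventricular cardiomyocytes, and most cardiomyocyte markers lay below the filter on low values. The cells were synchronized with a pulse of dexamethasone, a synthetic glucocorticoid used to align the circadian clocks of cells in culture. They were then left untreated or exposed to vehicle or to digoxin, a cardiac glycoside that inhibits the sodium potassium pump. RNA was profiled on 24 expression arrays in 8 groups of 3. Untreated cells were collected at T0 and T16, and cells given vehicle, 0.5 µM digoxin or 5 µM digoxin were collected at T4 and T20, where the number is the hour after synchronization. Per the sample labels, both treated times lay 4 h after treatment, while the growth protocol places the T20 collection 20 h after it. The protocol lists T16 in the same way, although only untreated cells were collected then, so its hours cannot all count from digoxin or vehicle. The design asks how digoxin changed gene expression at each dose, and whether the change differed between T4 and T20. If the labels hold, that difference is one of time after synchronization, and if the protocol holds, length of exposure differs as well and the 2 cannot be separated. All values are log2 gene values, differences are given with their standard error (SE) from the fit over 24 arrays, and 11764 genes were tested. The labels do not state that the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

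Replicates correlated at 0.9912 to 0.9954 across genes, against 0.9765 to 0.9944 for arrays of different groups. The first component of the gene values held 21.9% of the variance and the second 19.8%. Digoxin lowered both component scores at both times, and the 3 arrays of each group lay next to each other. Scores on the first component were 31.3 to 38.4 at T16 and 14.6 to 17.5 in the T20 vehicle arrays. At T20 they were -9.6 to -8.7 under 5 µM digoxin, and at T4 -24.9 to -24. The vehicle arrays at T4 scored 0.3 to 2.6. Because the number of arrays per group is 3, the precision is limited to a median SE of 0.139 for a difference between groups.

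**Figure D1:**
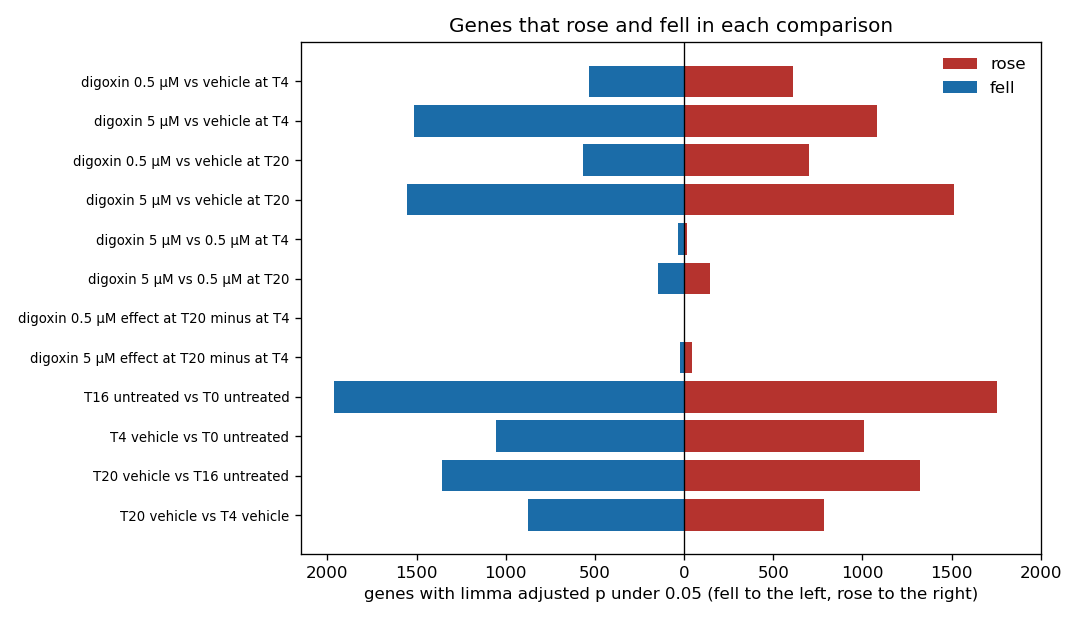
Number of genes with an adjusted p under 0.05 in each of the 12 comparisons, with genes that fell drawn to the left of 0 and genes that rose to the right. Under 5 µM digoxin 2594 genes changed at T4 and 3067 at T20, and the difference between the times passed for 67 genes.

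At T4, genes of the immediate early response and of the glucocorticoid response stood higher under 5 µM digoxin than in vehicle. Most members of both lists fell from T0 to the T4 vehicle, so for them a rise over vehicle may be a smaller fall. PER1, for example, was 10.08 under 5 µM, between 7.66 in the T4 vehicle and 13.18 at T0. IL11, an interleukin-6 family cytokine, rose by 3.20 ± 0.25 (adjusted p = 3.96e-08), and CXCL8, a neutrophil-attracting chemokine, by 2.59 ± 0.20. SLC19A2, a thiamine transporter, rose by 2.87 ± 0.14 (adjusted p = 1.21e-10). EGR1, an immediate early transcription factor, rose by 2.60 ± 0.15, SGK1, a kinase induced by serum and glucocorticoids, by 2.46 ± 0.17, the clock gene PER1 by 2.42 ± 0.21 and the cytokine IL24 by 2.34 ± 0.13. The vault RNA gene VTRNA1-1, read by 1 probe set, rose by 2.28 ± 0.41. EIF5, a translation initiation factor, fell by 2.54 ± 0.13 (adjusted p = 1.75e-10) and ARRDC3, an alpha-arrestin, (-2.15 ± 0.20). Among the other large decreases, the zinc finger gene ZFP69 fell by 2.14 ± 0.29, NHLRC1, the ubiquitin ligase malin, (-1.96 ± 0.19) and the pseudogene SUGT1P3 (-2.00 ± 0.48). ARRDC3 and SUGT1P3 rose from T0 to the T4 vehicle, so for them a value below that vehicle may be a smaller rise. RABGGTB (decreased by 2.80 ± 0.89), SNAR-E (-2.35 ± 0.54) and ADAM1A (-2.12 ± 0.22) rested on 1 probe set each.

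Of 11764 genes, 2594 passed in that comparison, 1080 higher and 1514 lower. The excess of decreases depended on the scaling. With each array centred on its median gene value, 1609 genes rose and 1131 fell.

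The fixed lists placed these genes in groups. Of 32 immediate early genes tested at T4, 20 rose and 2 fell under 5 µM digoxin (22 and 2 adjusted over the list alone), among them DUSP1, a MAP kinase phosphatase (2.12 ± 0.16), and ZFP36, an mRNA decay factor (1.72 ± 0.15). Camera placed the list above the other genes (adjusted p = 2.06e-11). Of 18 glucocorticoid targets 10 rose and none fell (10 and 1 adjusted over the list alone; camera adjusted p = 6.39e-10). SLC19A2, SGK1, DUSP1 and PER1 led that list, and 7 of its 18 members also stand in other lists. Of 26 inflammatory NF-kB targets 13 rose and 2 fell (14 and 4 adjusted over the list alone), with increases of NFKBIZ, a nuclear IkB protein (1.88 ± 0.16), and TNFAIP3, the A20 inhibitor of NF-kB signalling (1.57 ± 0.14). The camera adjusted p was 7.26e-07, and the adjusted p = 0.0547 with an estimated correlation. Of 20 genes of sterol synthesis and uptake 8 rose, both over all genes and adjusted over the list alone, including INSIG1, which retains the sterol sensor in the endoplasmic reticulum (1.77 ± 0.09), the sterol carrier STARD4 (1.08 ± 0.12) and HMGCS1, a cholesterol synthesis enzyme (0.80 ± 0.11). For this list the camera adjusted p was 0.00187, and the adjusted p = 0.315 with an estimated correlation. Of 13 replication-dependent histone genes 6 rose and 1 fell (the same counts adjusted over the list alone), such as H2BC17 (1.04 ± 0.27) and H1-2 (0.70 ± 0.15), with a camera adjusted p of 0.0259 and an adjusted p = 0.377 with an estimated correlation.

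Other genes changed by 5 µM digoxin at T4 stood in lists that did not pass as a whole. PPP1R15A, which restores translation after stress, rose by 1.99 ± 0.16, the stress cytokine GDF15 by 1.88 ± 0.20 and the pro-apoptotic gene PMAIP1 by 1.65 ± 0.12. CCN2, a matricellular growth factor that also stands in the immediate early list, rose by 1.60 ± 0.17, and CDC25A, a phosphatase of the cell cycle, by 1.13 ± 0.11. CPT2, an enzyme of mitochondrial fatty acid oxidation, fell by 1.34 ± 0.12, SKP2, an F-box protein of a ubiquitin ligase, (-1.18 ± 0.09) and POLR1B, a subunit of RNA polymerase I, (-0.92 ± 0.12).

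At 0.5 µM and T4, IL11 rose by 2.75 ± 0.25 (adjusted p = 1.06e-06), SLC19A2 by 1.85 ± 0.14 and CXCL8 by 1.83 ± 0.20. Further increases were those of SGK1 by 1.74 ± 0.17, GDF15 by 1.72 ± 0.20, IL24 by 1.71 ± 0.13, EGR1 by 1.62 ± 0.15 and DUSP1 by 1.56 ± 0.16. EIF5 fell by 2.39 ± 0.13 (adjusted p = 1.20e-09), ARRDC3 (-2.23 ± 0.20), FAM13B (-1.78 ± 0.10) and MOCS2, a molybdenum cofactor synthesis gene, (-1.45 ± 0.15). The zinc finger genes ZNF253 (decreased by 1.94 ± 0.52), ZNF33B (-1.55 ± 0.32) and ZNF19 (-1.52 ± 0.24) fell as well, as did SNAR-E (-2.44 ± 0.54). In all, 1148 genes passed, 613 higher and 535 lower. Without replicate 1 of the T4 vehicle 756 genes passed. Of the fixed lists, glucocorticoid targets (10 of 18 rose, also adjusted over the list alone; camera adjusted p = 4.27e-09) kept their call with an estimated correlation (adjusted p = 0.00742). The immediate early genes (12 rose and 2 fell of 32, and 17 and 4 adjusted over the list alone; camera adjusted p = 4.51e-07) had an adjusted p = 0.186 with an estimated correlation. The NF-kB targets (9 rose of 26, and 12 rose with 1 decrease adjusted over the list alone; camera adjusted p = 4.72e-05) had an adjusted p = 0.186 with an estimated correlation. The sterol list (5 of 20 rose, and 6 adjusted over the list alone; camera adjusted p = 7.21e-04) had an adjusted p = 0.292 with an estimated correlation. Autophagy and lysosome genes (2 of 27 rose, TFE3 by 0.62 ± 0.13 and GABARAPL1 by 0.59 ± 0.16, and 3 adjusted over the list alone; camera adjusted p = 0.0275) had an adjusted p = 0.186 with an estimated correlation.

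At T20, 5 µM digoxin raised immediate early genes, which respond within minutes to hours of a stimulus. CCN2 rose by 4.01 ± 0.17 (adjusted p = 7.72e-12) and EGR1 by 3.90 ± 0.15 (adjusted p = 2.85e-12). LIF, an interleukin-6 family cytokine, rose by 3.82 ± 0.21, IL11 by 3.68 ± 0.25 and NR1D1, the nuclear receptor REV-ERB alpha that represses clock genes, by 3.48 ± 0.26. CXCL8 rose by 3.25 ± 0.20, DUSP1 by 3.09 ± 0.16 and the inflammatory cytokine IL1A by 2.94 ± 0.22. EIF5 fell by 2.59 ± 0.13 (adjusted p = 5.02e-11), EEF2K, the kinase of elongation factor 2, (-2.31 ± 0.13), MOCS2 (-2.22 ± 0.15) and NHLRC1 (-2.00 ± 0.19). ZFP69 fell by 2.59 ± 0.29, the zinc finger gene ZNF30 (-2.35 ± 0.31), NBPF1 (-2.13 ± 0.26) and SLC35A1, a sialic acid transporter, (-2.57 ± 0.92) (2 probe sets, adjusted p = 0.0458). NBPF1 belongs to a family of near-identical copies, so its value is uncertain.

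In the 5 µM comparison at T20, 3067 genes passed, 1513 higher and 1554 lower. The control RNAs added to every sample stood higher in these arrays than in the vehicle arrays, by 0.70 for the poly-A controls and 0.69 for the hybridization controls, and by 0.31 and 0.48 at 0.5 µM. Scaled to the poly-A controls, the median of all genes moved by -0.70 at 5 µM and T20, by -0.29 at 0.5 µM and T20, by -0.26 at 5 µM and T4 and by -0.10 at 0.5 µM and T4. All changes are therefore stated relative to the other probe sets, since quantile normalization gave every array the same distribution of values. On the scale of the poly-A controls 145 genes rose and 9420 fell at 5 µM and T20, and 124 and 2424 at 0.5 µM and T20. At T4 the counts on that scale were 229 and 2831 at 5 µM and 136 and 458 at 0.5 µM.

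Of 32 immediate early genes, 26 rose and 1 fell at 5 µM and T20 (27 and 1 adjusted over the list alone; camera adjusted p = 1.80e-21), including FOS (2.55 ± 0.20). Of 26 NF-kB targets 20 rose and none fell (22 and 1 adjusted over the list alone; camera adjusted p = 1.58e-18), including TNFAIP3 (2.75 ± 0.14) and IL6 (2.55 ± 0.15). Of 18 glucocorticoid targets 10 rose and 2 fell (10 and 3 adjusted over the list alone; camera adjusted p = 2.86e-07), including BCL6, a transcriptional repressor (2.07 ± 0.10), SLC19A2 (2.02 ± 0.14) and ERRFI1, a feedback inhibitor of EGF receptors (1.15 ± 0.08). These lists and the clock list held with an estimated correlation, with adjusted p = 0.00198 for the first pair and 0.00694 for glucocorticoid targets and clock genes. Of 20 sterol genes 10 rose (12 adjusted over the list alone; camera adjusted p = 4.23e-07), HMGCS1 by 1.53 ± 0.11, INSIG1 by 1.42 ± 0.09 and MSMO1, a C4-methylsterol oxidase, by 1.11 ± 0.12, with an adjusted p = 0.0828 with an estimated correlation. The medians of these 5 lists lay 0.42 to 1.18 above 0, against the 0.70 by which the poly-A controls moved, and scaled to those controls the sterol and clock medians were below 0.

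The other 30 lists did not pass at 5 µM and T20, although members of most changed. Among genes of the p53 response (5 rose and 3 fell of 23; camera adjusted p = 0.25), PMAIP1 rose by 1.76 ± 0.12 and GADD45A by 1.14 ± 0.09, and PLK2 fell by 0.77 ± 0.10. Among apoptosis regulators (8 rose and 3 fell of 23; camera adjusted p = 0.156), BIRC3 rose by 1.91 ± 0.17 and MCL1 by 1.03 ± 0.09, both known to oppose cell death, and CASP8, an initiator caspase, fell by 0.96 ± 0.14. Of 29 targets of ATF4 and the integrated stress response, 5 rose and 8 fell (camera adjusted p = 0.445). GDF15 rose by 2.42 ± 0.20 and PPP1R15A by 1.90 ± 0.16, while CHAC1, a glutathione-degrading enzyme, fell by 1.73 ± 0.16 and PSAT1, of serine synthesis, (-0.81 ± 0.12). HERPUD1 fell by 0.81 ± 0.10 in the unfolded protein response list (3 rose and 1 fell of 22; camera adjusted p = 0.445), and BAG3 (-0.48 ± 0.09) in the heat shock list (1 rose and 5 fell of 16; camera adjusted p = 0.177). The heat shock members HSPA1A, HSPA1B and HSPA8, without a probe set of that symbol alone, and HSPA6, HSPB8 and CRYAB, below the filter, were not tested. In the ubiquitin list (5 rose and 3 fell of 24; camera adjusted p = 0.299) SMURF1 rose by 1.19 ± 0.09 and SKP2 fell by 0.71 ± 0.09. Of 25 splicing factors 7 rose and 4 fell (camera adjusted p = 0.652), the kinases CLK4 by 1.57 ± 0.20 and CLK1 by 1.01 ± 0.19 upward and SRSF6 (-0.82 ± 0.11). The glucose transporter SLC2A3 rose by 1.68 ± 0.15 in the glycolysis and hypoxia list (4 rose and 4 fell of 31; camera adjusted p = 0.8).

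Of ribosome biogenesis genes at 5 µM and T20, 2 rose and 6 fell of 26 (camera adjusted p = 0.36), UBTF (-0.75 ± 0.13), and of ribosomal protein genes 4 rose and 4 fell of 29 (camera adjusted p = 0.881; median 0.06, mean -0.01). In the interferon response list 1 rose and 5 fell of 18 (camera adjusted p = 0.445), IFIT3 (-1.04 ± 0.17). Of 28 genes of TGF-beta and matrix 5 rose and 5 fell (camera adjusted p = 0.636), and of 9 metallothionein and zinc genes 1 rose and 2 fell (camera adjusted p = 0.632), the zinc exporter SLC30A1 (-0.86 ± 0.12). Fatty acid synthesis had 4 genes higher and 2 lower of 14 (camera adjusted p = 0.436), autophagy and lysosome 6 and 2 of 27 (0.426) and calcium handling 5 and 1 of 20 (0.25). Oxidative phosphorylation had 3 and 0 of 29 (0.445), mitochondrial biogenesis and fatty acid oxidation 3 and 1 of 16 (0.632), the NRF2 response 1 and 1 of 18 (0.579) and proteasome subunits 2 and 1 of 31 (0.631). G2 and mitosis genes had 6 higher and 3 lower of 33 (camera adjusted p = 0.276), G1 to S genes 4 and 2 of 32 (0.445), KRAB zinc finger genes 4 and 4 of 37 (0.81) and histone genes 1 and 2 of 13 (0.961; median 0.06, mean -0.02). Among markers of cell types, 6 of the 31 cardiomyocyte markers on the array passed the filter on low values, and 1 rose (camera adjusted p = 0.961). Fibroblast markers were tested for 15 of 19 and none passed (camera adjusted p = 0.8), smooth muscle markers for 6 of 13, with 2 higher and 1 lower (0.426), and endothelial and leukocyte markers for 1 gene each, without a change (0.986 and 0.632).

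At 0.5 µM and T20, EGR1 rose by 2.82 ± 0.15 (adjusted p = 4.67e-10), CCN2 by 2.51 ± 0.17 and IL11 by 2.47 ± 0.25. Other increases were those of DUSP1 by 2.32 ± 0.16, CXCL8 by 2.20 ± 0.20, LIF by 2.03 ± 0.21 and SGK1 by 1.98 ± 0.17. SENP3, a SUMO protease read by 1 probe set, rose by 2.25 ± 0.67. EIF5 fell by 2.66 ± 0.13 (adjusted p = 2.18e-10), FAM13B (-1.84 ± 0.10), ARRDC3 (-1.83 ± 0.20), the kinase gene TAOK2 (-1.56 ± 0.14) and the non-coding gene SNHG7 (-1.69 ± 0.30). The zinc finger genes ZNF30 (decreased by 1.80 ± 0.31) and ZNF786 (-1.73 ± 0.33) and the ribosomal protein gene RPL3 (-1.66 ± 0.34), which has many near-identical copies, fell too. In all, 1267 genes passed, 703 higher and 564 lower. Immediate early genes (21 rose and 1 fell of 32, and 23 and 1 adjusted over the list alone; camera adjusted p = 7.73e-17), NF-kB targets (13 and 1 of 26, and 16 and 1 adjusted over the list alone; camera adjusted p = 1.19e-10) and glucocorticoid targets (10 and 2 of 18, the same adjusted over the list alone; camera adjusted p = 2.04e-07) each kept their call with an estimated correlation (adjusted p = 0.0123). Sterol genes (8 of 20 rose, also adjusted over the list alone; camera adjusted p = 5.34e-06) had an adjusted p = 0.114 with an estimated correlation. G2 and mitosis genes (3 of 33 rose, and 4 adjusted over the list alone; camera adjusted p = 0.025) had an adjusted p = 0.406 with an estimated correlation, and apoptosis regulators (5 of 23 rose, and 5 with 1 decrease adjusted over the list alone; camera adjusted p = 0.025) an adjusted p = 0.0984 with an estimated correlation.

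Genes of the circadian clock were followed in every comparison. PER1 stood at 13.18 ± 0.08 (SD, n = 3) at T0 and at 7.66 ± 0.07 in the T4 vehicle. At T4 it was 9.12 ± 0.40 under 0.5 µM and 10.08 ± 0.36 under 5 µM digoxin, and at T20 it was 8.26 ± 0.13 in vehicle and 10.89 ± 0.15 under 5 µM. NR1D1 was 4.76 ± 0.11 in vehicle and 5.99 ± 0.20 under 5 µM at T4, and 7.22 ± 0.20 and 10.70 ± 0.36 at T20. Its means at T4 lay at or below the median gene value of 6, the limit of the filter on low values, where differences are less certain. With the probe set of highest mean alone, NR1D1 differed at T20 by -0.19 under 5 µM and -0.73 under 0.5 µM, so its rise rested on its other probe sets. Its paralog NR1D2 rose under 5 µM by 1.07 ± 0.12 at T4 and 0.54 ± 0.12 at T20. CRY1, a repressor of the clock, fell under 5 µM at T4 (-1.22 ± 0.14) and T20 (-0.63 ± 0.14). Under 0.5 µM it fell at both times as well (-0.80 ± 0.14 and -1.08 ± 0.14). NFIL3 rose by 0.57 ± 0.13 and 1.12 ± 0.13, BHLHE40 rose at T20 by 0.99 ± 0.17 and PER2 at T20 by 1.23 ± 0.24. BMAL1, the transcriptional activator of the clock, differed by -0.25 ± 0.14 at T4 and 0.31 ± 0.14 at T20 and did not pass (adjusted p = 0.225 and 0.111), and CLOCK did not pass either (0.20 ± 0.08 and 0.17 ± 0.08). Smaller increases at T20 were those of CRY2 (0.49 ± 0.13), CIART (0.54 ± 0.17), CSNK1E (0.42 ± 0.09) and TEF (0.42 ± 0.14), and CSNK1D fell by 0.36 ± 0.08. On the scale of the poly-A controls the differences of NR1D2, CRY2, CIART, CSNK1E, TEF, BMAL1 and CLOCK at 5 µM and T20 were below 0. As a list, 7 of 19 clock genes rose and 1 fell at 5 µM and T4 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.0434 with an estimated correlation). At 5 µM and T20, 10 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 9.81e-04). At 0.5 µM the list did not pass at T4 (4 rose and 1 fell; camera adjusted p = 0.163) or at T20 (6 rose and 1 fell; camera adjusted p = 0.0567). The difference between times did not pass for the list at 5 µM (1 gene higher; camera adjusted p = 0.241) or at 0.5 µM (no gene; camera adjusted p = 0.903).

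**Figure D2:**
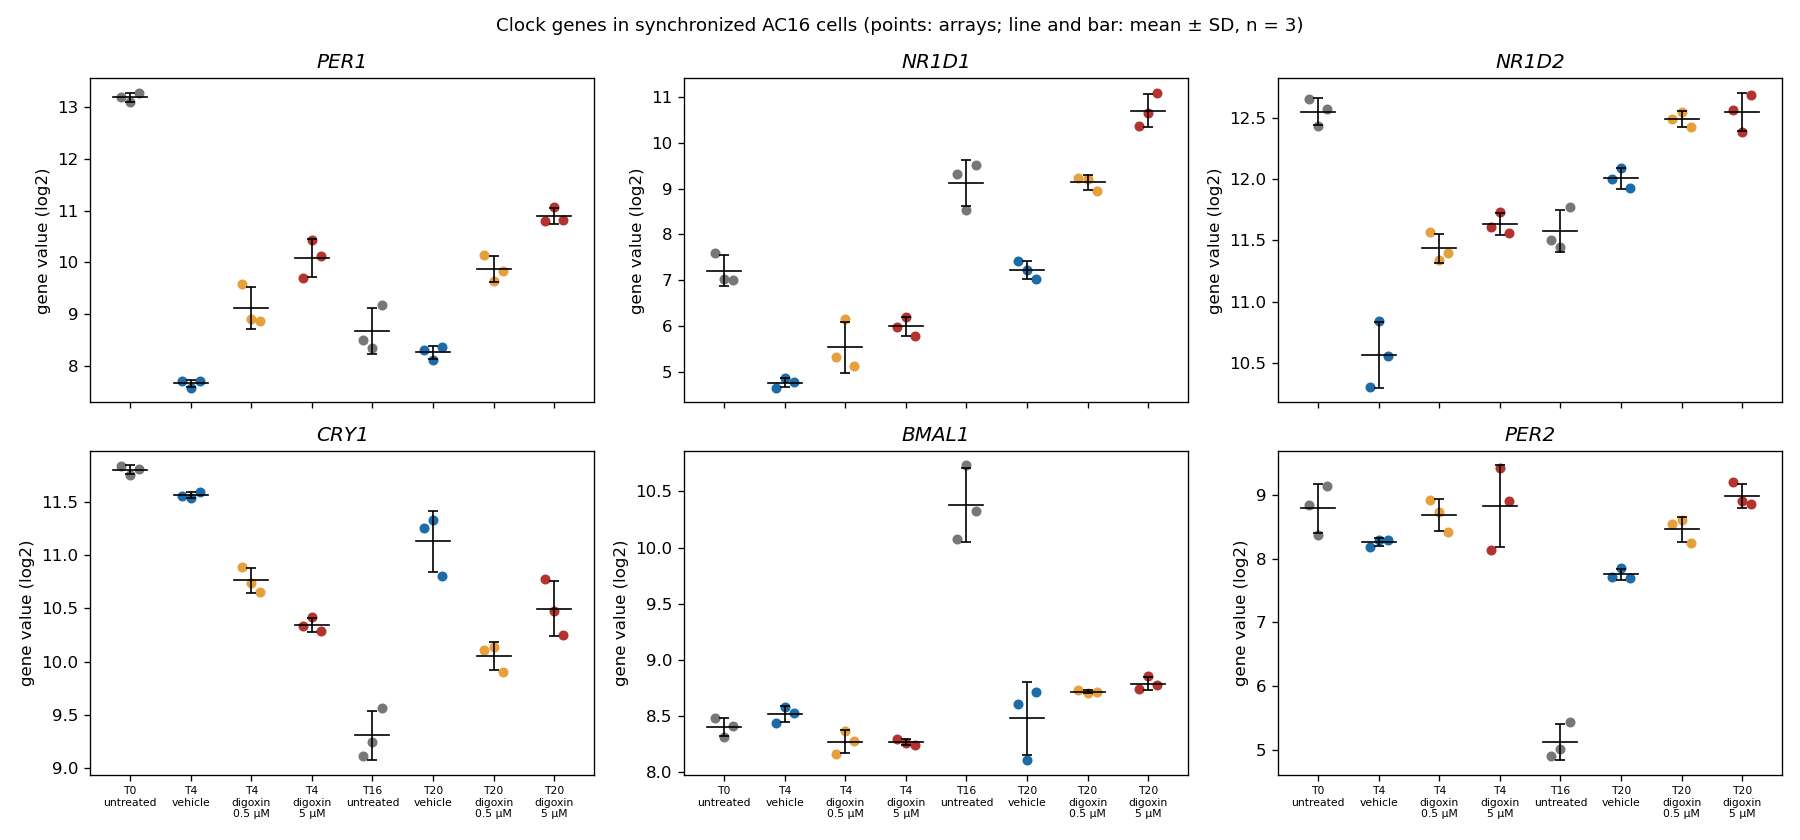
Log2 values of 6 clock genes on the 24 arrays, with each point an array and the line and bar the mean ± SD of the 3 arrays of a group (untreated grey, vehicle blue, 0.5 µM digoxin orange, 5 µM red). NR1D1 under 5 µM digoxin reached 10.70 at T20, above the vehicle mean of 7.22, and PER1 at T0, 13.18, lay above all later groups.

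Of the sodium potassium pump, the target of digoxin, 3 genes were tested. The beta subunit gene ATP1B1 rose under 5 µM by 0.57 ± 0.08 at T4 (adjusted p = 3.56e-05) and 0.34 ± 0.08 at T20 (adjusted p = 0.00337), where it was -0.36 on the scale of the poly-A controls. Under 0.5 µM it differed by 0.18 ± 0.08 and 0.21 ± 0.08 and did not pass. ATP1B3 rose by 0.28 ± 0.09 at 5 µM and T4 (adjusted p = 0.0276), and FXYD5 did not pass in any digoxin comparison. As a list the pump genes did not pass at 5 µM and T20 (1 of 3 rose; camera adjusted p = 0.491).

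Between the doses at T20, 5 µM exceeded 0.5 µM for inflammatory and immediate early genes. IL1A was higher by 1.98 ± 0.22 (adjusted p = 4.83e-05), LIF by 1.79 ± 0.21, RHOB, a small GTPase, by 1.64 ± 0.15 and NR1D1 by 1.57 ± 0.26. Higher too were CCN2 by 1.5 ± 0.17, TNFAIP3 by 1.48 ± 0.14 and IL6 by 1.36 ± 0.15. EEF2K was lower at the higher dose (decreased by 1.16 ± 0.13), as were TRIM27 (-1.25 ± 0.14), PPP6R1 (-1.3 ± 0.15), GLYATL2 (-1.32 ± 0.26) and ZNF429 (-1.84 ± 0.46). In all, 289 genes passed, 144 higher and 145 lower at 5 µM, and scaled to the poly-A controls, which moved the median gene by -0.41, 32 higher and 5191 lower. Without replicate 1 of T20 5 µM digoxin 143 genes passed. In a fit of only the groups compared 12 passed, 10 higher and 2 lower, with the probe set of highest mean 117, with no filter 139 and with the mean of the probe sets 161. Of 26 NF-kB targets 13 were higher (18 adjusted over the list alone; camera adjusted p = 3.37e-24), and of 32 immediate early genes 8 (18 adjusted over the list alone; 1.08e-16). Of 18 glucocorticoid targets 7 were higher (9, with 1 lower, adjusted over the list alone; 1.27e-06) and of 19 clock genes 3 (4 adjusted over the list alone; 1.15e-04). These 4 lists held with an estimated correlation. Sterol genes (3 of 20 higher, and 4 adjusted over the list alone; camera adjusted p = 3.35e-04) had an adjusted p = 0.294 with an estimated correlation. Heat shock genes moved lower as a list although none of 16 passed over all genes (3 lower adjusted over the list alone; camera adjusted p = 0.00107, and adjusted p = 0.155 with an estimated correlation). The direction is that of the members tested, which did not include HSPA1A, HSPA1B, HSPA6, HSPA8, HSPB8 or CRYAB.

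Between the doses at T4, 52 genes passed, 16 higher and 36 lower at 5 µM. With each array centred on its median gene value the split was 34 higher and 17 lower, with cyclic loess 23 and 26, and on the scale of the poly-A controls, where the median gene moved by -0.17, 2 and 13. Without replicate 2 of T4 0.5 µM digoxin 5 genes passed. None passed in a fit of only the groups compared, 1 with the probe set of highest mean, 7 with no filter, 20 with the replicate block and 21 with the mean of the probe sets, while 80 passed with eBayes with trend and robust and 232 with array weights. Higher at 5 µM were VTRNA1-1 (2.48 ± 0.41), ANKRD1, a stress-responsive cardiac ankyrin repeat gene (1.09 ± 0.22), SLC19A2 (1.02 ± 0.14), EGR1 (0.98 ± 0.15), PER1 (0.96 ± 0.21) and INSIG1 (0.64 ± 0.09). ATP1B1 was also higher at 5 µM (0.39 ± 0.08). Lower were ZNF546 (-1.20 ± 0.24), EEF2K (-1.0 ± 0.13, but 0.99 with the probe set of highest mean alone), TUBA3FP (-0.96 ± 0.18), CNPY2 (-0.93 ± 0.13) and NHLRC1 (-0.89 ± 0.19). Immediate early genes (2 of 32 higher, and 7 adjusted over the list alone; camera adjusted p = 1.69e-10) and glucocorticoid targets (2 of 18, and 8 adjusted over the list alone; 2.06e-07) held with an estimated correlation (adjusted p = 0.0473 and 0.0228). NF-kB targets (1 of 26, and 6 adjusted over the list alone; camera adjusted p = 3.14e-05), clock genes (1 of 19 in both counts; 0.0357) and histone genes (0 of 13, with 1 lower adjusted over the list alone; 6.98e-04) did not, with adjusted p = 0.13, 0.0907 and 0.259 with an estimated correlation. The median of the histone list was 0.30.

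The effect of 5 µM digoxin differed between T20 and T4 for 67 genes, 47 of them with the higher difference at T20. The largest was LIF, by 2.73 ± 0.30 (adjusted p = 8.69e-05), followed by IL1A (2.66 ± 0.32), EDN1, the vasoconstrictor endothelin 1 (2.58 ± 0.35), CCN2 (2.41 ± 0.24) and NR1D1 (2.26 ± 0.37, but -3.39 with the probe set of highest mean alone). The T4 means of NR1D1, 4.76 and 5.99, lay at or below the filter limit of 6, so its value is less certain. Cytokine genes IL1B (1.76 ± 0.24) and CCL2 (1.54 ± 0.20), the immediate early genes FOS (1.48 ± 0.28), EGR1 (1.3 ± 0.21) and MYC (0.88 ± 0.18), GADD45A, a growth arrest gene (1.37 ± 0.13), BIRC3 (1.51 ± 0.24), BCL6 (1.06 ± 0.15) and HMGCS1 (0.74 ± 0.16) also differed in that direction. In the other direction were ZNF480 (-1.65 ± 0.37), RGCC, a regulator of the cell cycle (-1.53 ± 0.24), CCN4, a target of Wnt signalling (-1.41 ± 0.16), CHAC1 (-1.23 ± 0.23) and BAMBI, a decoy receptor for TGF-beta ligands (-1.22 ± 0.25). The poly-A controls differed by 0.45 in this comparison and the hybridization controls by 0.6. Scaled to the poly-A controls, the median of all genes moved by -0.43, with 14 genes in the first direction and 466 in the second. With each array centred on its median gene value the split was 35 and 35. The count was 42 without replicate 1 of the T4 vehicle, 39 and 37 without replicates 1 and 3 of T4 5 µM digoxin and 42 without replicate 1 of T20 5 µM digoxin. It was 31 in a fit of only the groups compared and 32 with the mean of the probe sets. At 0.5 µM the difference between times passed for 1 gene, CCN4 (-1.07 ± 0.16, adjusted p = 0.0299), and for 661 genes at an unadjusted p under 0.05 (limma). With each array centred on its median gene value or with quantile normalization of gene values 2 genes were higher and 1 lower, with cyclic loess 1 and 1, and on the scale of the poly-A controls, with a median shift of -0.19, none passed.

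As lists, NF-kB targets (7 of 26 higher, and 13 with 1 lower adjusted over the list alone; camera adjusted p = 1.28e-15) and immediate early genes (4 of 32, and 18 adjusted over the list alone; 3.52e-12) differed between times at 5 µM and held with an estimated correlation (adjusted p = 0.0056 and 0.0294). Sterol genes (1 of 20 higher, and 2 adjusted over the list alone; camera adjusted p = 0.0177) had an adjusted p = 0.68 with an estimated correlation. ATF4 targets (1 of 29 lower, and 3 lower with 1 higher adjusted over the list alone; camera adjusted p = 0.0177) and histone genes (0 of 13, with 1 lower adjusted over the list alone; 0.00169) lay in the other direction, with adjusted p = 0.16 and 0.305 with an estimated correlation. At 0.5 µM, immediate early genes (0 of 32 and, adjusted over the list alone, 6 higher; camera adjusted p = 2.35e-09) and NF-kB targets (0 of 26 and 4; 0.00293) had adjusted p = 0.143 and 0.769 with an estimated correlation.

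**Figure D3:**
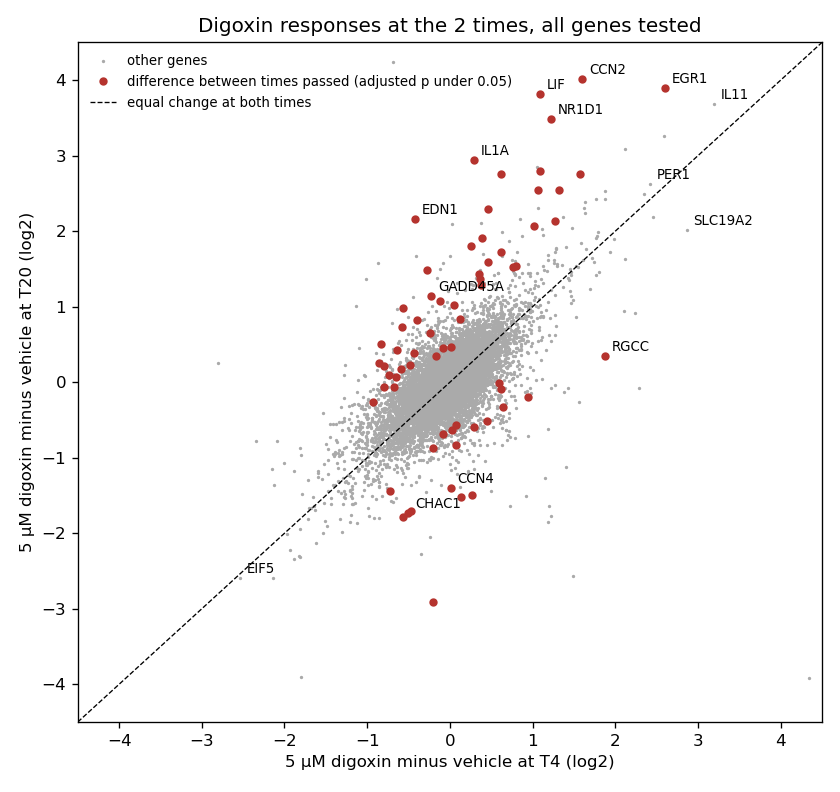
Change of each of 11764 genes under 5 µM digoxin at T4 (horizontal axis) and at T20 (vertical axis), in log2 units, with the 67 genes whose change differed between the times in red. LIF, CCN2 and NR1D1 lie above the dashed line of equal change, by 2.73, 2.41 and 2.26.

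The responses at the 2 times were compared across genes, which are not independent replicates. Under 5 µM the log2 changes correlated with r = 0.67 (Spearman rho 0.64), and 728 genes rose and 896 fell at both times, against 138.9 and 200 for independent lists. Genes passing at both times in opposite directions numbered 4. Under 0.5 µM r was 0.62, with 344 rising and 285 falling at both times against 36.6 and 25.6. These pairs share no arrays, and r was 0 in simulated unchanged groups. Between doses r was 0.81 at T4 and at T20, but those comparisons share their vehicle arrays, and unchanged groups simulated against shared controls gave r = 0.5. The covariance at T4 was 0.105 against 0.0204 simulated, and at T20 0.123 against 0.0206. The simulation covers the sharing only at the spread between replicates. A shift common to the 3 vehicle arrays would add to the excess, and these arrays cannot be split into 2 sets of at least 2 to test it.

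Independent of digoxin, the hours after dexamethasone changed many genes. From T0 to T16 in untreated cells, INSIG1 rose by 2.62 ± 0.09, HMGCS1 by 3.14 ± 0.11, MSMO1 by 2.66 ± 0.12 and HSD17B7 by 2.57 ± 0.30, all of cholesterol metabolism, and ARRDC3 by 3.18 ± 0.20. ANKRD1 fell by 6.70 ± 0.22 (adjusted p = 2.43e-14), the metallothionein MT1E (-5.87 ± 0.34), the phosphatase DUSP5 (-5.44 ± 0.18), CCN2 (-5.11 ± 0.17) and SLC19A2 (-4.66 ± 0.14). In all, 3716 genes passed, 1754 higher and 1962 lower, and 446 and 3106 on the scale of the poly-A controls, where the median gene moved by -0.24. Of 18 glucocorticoid targets 13 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 5.10e-14). Of 32 immediate early genes 27 fell and 1 rose (27 and 1; 2.84e-19), and of 20 sterol genes 19 rose (19, with 1 decrease; 9.03e-21). Of 14 genes of fatty acid synthesis 9 rose and 2 fell (10 and 2; 1.28e-05), FASN by 2.09 ± 0.14 upward. Ribosome biogenesis genes fell in 24 of 26 (24; 3.76e-14), NOLC1 (-0.77 ± 0.09), and 5 of 9 metallothionein and zinc genes fell (7; 2.66e-05). Fibroblast markers rose in 11 of 15 (12; 4.75e-10), COL1A2 by 2.34 ± 0.12 and PDGFRB by 2.26 ± 0.15. These lists, with the clock list and the ATF4 targets (5 rose and 15 fell of 29, and 5 and 16; 0.00459), held with an estimated correlation. The lists of G2 and mitosis (14 rose and 2 fell of 33), interferon response (11 rose of 18), NF-kB targets (5 rose and 10 fell of 26), ribosomal proteins (12 fell of 29) and histones (7 fell of 13) passed with the preset correlation only, with adjusted p = 0.168, 0.175, 0.288, 0.175 and 0.0954 with an estimated correlation.

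Clock genes from T0 to T16 fell in 13 of 19 cases and rose in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 1.49e-05). PER1 fell by 4.51 ± 0.21, PER2 (-3.65 ± 0.24), CRY1 (-2.5 ± 0.14) and PER3 (-2.19 ± 0.15), and BMAL1 rose by 1.98 ± 0.14 and NR1D1 by 1.92 ± 0.26.

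From T0 to the T4 vehicle, 2062 genes passed, 1010 higher and 1052 lower, in a comparison where time and vehicle cannot be separated. ANKRD1 fell by 5.88 ± 0.22, PER1 (-5.52 ± 0.21), DUSP5 (-5.47 ± 0.18), CCN2 (-4.94 ± 0.17) and DUSP1 (-4.37 ± 0.16). ARRDC3 rose by 3.31 ± 0.20, HAS2, a hyaluronan synthase, by 2.25 ± 0.21, SUGT1P3 by 2.13 ± 0.48, the chemokine CCL2 by 1.92 ± 0.14 and HMGN2 by 1.72 ± 0.11. Immediate early genes fell in 25 of 32 and rose in 2 (the same adjusted over the list alone; camera adjusted p = 3.63e-26). Clock genes fell in 10 of 19 and rose in 1 (11 and 2; 5.81e-10), and glucocorticoid targets fell in 11 of 18 and rose in 4 (11 and 4; 2.36e-09). These held with an estimated correlation. Sterol genes (6 of 20 fell), glycolysis and hypoxia genes (8 fell and 1 rose of 31), NF-kB targets (10 rose and 3 fell of 26) and KRAB zinc finger genes (6 rose and 1 fell of 37) passed with the preset correlation only, with adjusted p = 0.224, 0.282, 0.498 and 0.282 with an estimated correlation.

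From T16 to the T20 vehicle, where time and vehicle again change together, IL6 rose by 2.68 ± 0.15, PER2 by 2.63 ± 0.24, SERPINB2 by 2.52 ± 0.30, SLC30A1 by 2.37 ± 0.12 and SLC16A6 by 2.32 ± 0.20. BMAL1 fell by 1.90 ± 0.14, NR1D1 (-1.90 ± 0.26), PARPBP (-1.64 ± 0.42), TMEM187 (-1.64 ± 0.17) and UBALD2 (-1.56 ± 0.22). In all, 2683 genes passed, 1325 higher and 1358 lower. In the T20 vehicle arrays the poly-A controls differed by -0.43 and the hybridization controls by -0.47. Scaled to the poly-A controls, 5252 genes rose and 113 fell around a median shift of 0.41. NF-kB targets rose in 20 of 26 (22 adjusted over the list alone; camera adjusted p = 7.85e-16), and G2 and mitosis genes fell in 19 of 33 (21; 1.63e-09). G1 to S genes rose in 11 of 32 (13; 6.82e-05), CCNE2 by 0.98 ± 0.07, and ATF4 targets rose in 12 and fell in 3 of 29 (12 and 3; 1.64e-04), SLC7A11 by 1.81 ± 0.14. These 4 held with an estimated correlation. Of the clock list, 10 rose and 4 fell of 19, PER3 by 2.28 ± 0.15 and CRY1 by 1.82 ± 0.14 upward (camera adjusted p = 0.0404, and adjusted p = 0.0834 with an estimated correlation). Ribosome biogenesis (15 of 26 rose), TGF-beta and matrix (10 rose and 1 fell of 28), interferon response (8 of 18 rose), glucocorticoid targets (7 rose and 1 fell of 18), sterol genes (7 of 20 fell) and splicing factors (10 rose and 3 fell of 25) passed with the preset correlation only, with adjusted p = 0.0834, 0.0834, 0.175, 0.219, 0.22 and 0.296 with an estimated correlation.

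Between the vehicle groups, 1656 genes differed at T20 from T4, 783 higher and 873 lower, and on the scale of the poly-A controls, with a median shift of 0.10, 711 higher and 103 lower. INSIG1 was higher by 3.17 ± 0.09, HMGCS1 by 3.03 ± 0.11, MSMO1 by 2.58 ± 0.12, SCD, a fatty acid desaturase, by 2.48 ± 0.15 and NR1D1 by 2.46 ± 0.26. SLC7A2 was lower (decreased by 3.01 ± 0.20), as were MT1M (-2.46 ± 0.39), MT1G (-2.07 ± 0.27), SENP3 (-2.06 ± 0.67) and CRISPLD2 (-2.06 ± 0.15). With an estimated correlation, sterol synthesis (18 of 20 higher, and 19 adjusted over the list alone; camera adjusted p = 1.21e-37), fatty acid synthesis (9 higher and 2 lower of 14; 1.05e-08) and interferon response (15 of 18 higher; 8.95e-16) held. So did fibroblast markers (10 of 15 higher; 4.87e-13), TGF-beta and matrix (13 higher and 1 lower of 28; 1.24e-07), metallothioneins and zinc (5 of 9 lower; 2.38e-06), glycolysis and hypoxia (8 of 31 higher; 4.64e-05) and clock genes (8 higher and 2 lower of 19; 3.20e-04). Ribosome biogenesis (13 of 26 lower), ribosomal proteins (4 of 29 lower), NF-kB targets (6 of 26 higher), smooth muscle markers (2 of 6 higher), histones (3 of 13 lower), the unfolded protein response (3 higher and 2 lower of 22), heat shock genes (2 higher and 7 lower of 16) and the NRF2 response (4 higher and 1 lower of 18) passed with the preset correlation only. Their adjusted p with an estimated correlation was 0.0886, 0.217, 0.194, 0.139, 0.252, 0.282, 0.282 and 0.252.

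**Figure D4:**
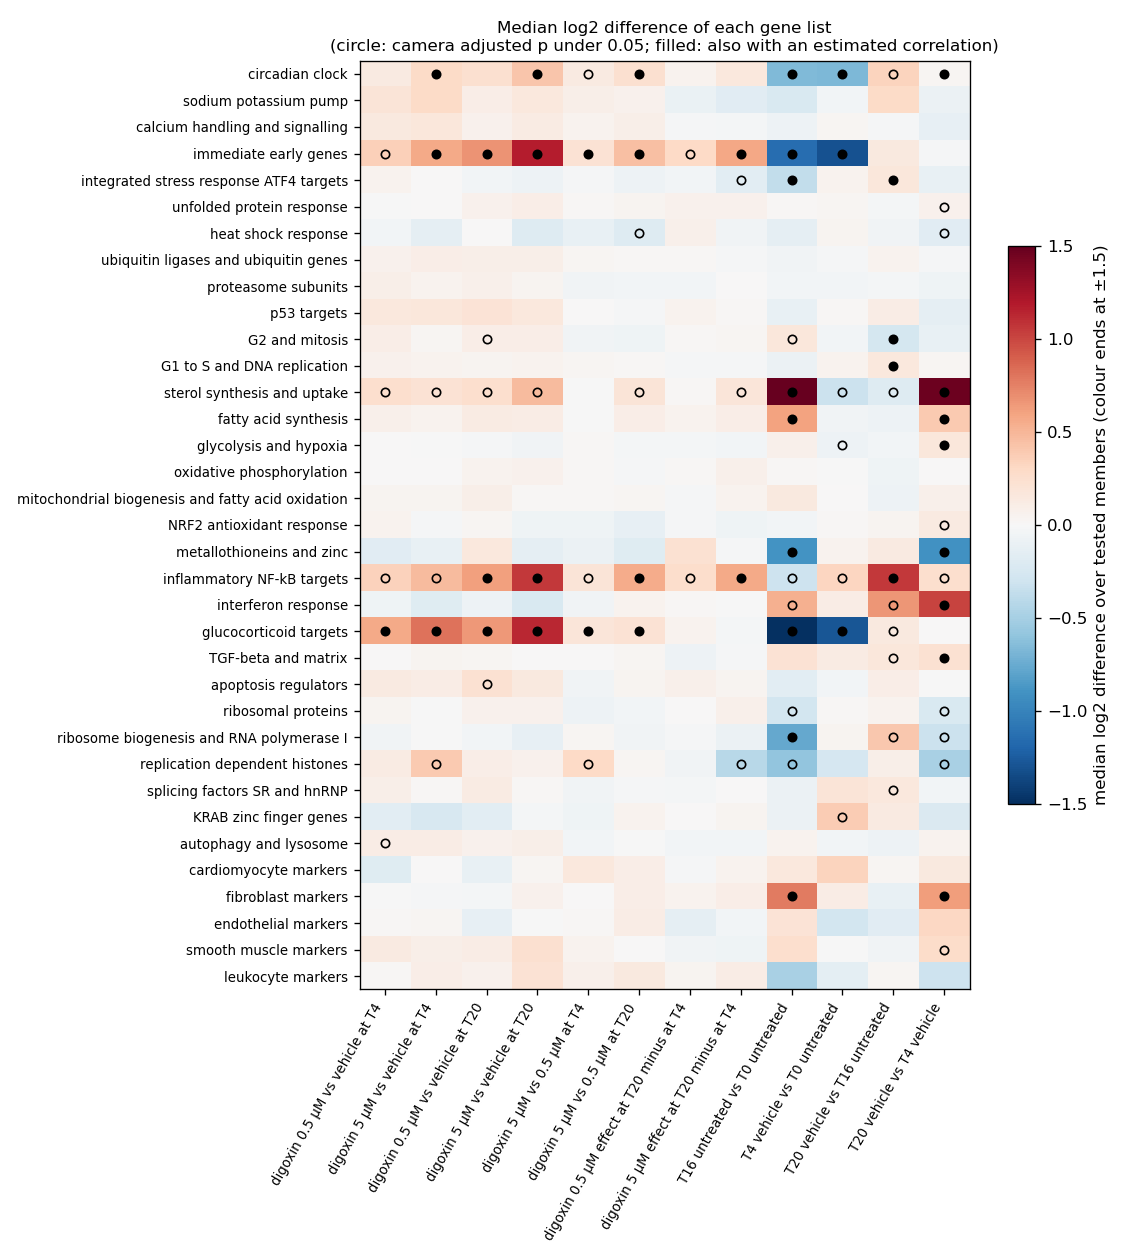
Median log2 difference of each of 35 gene lists (vertical axis) in each of the 12 comparisons (horizontal axis), in red above 0 and blue below 0, with circles for lists past the camera threshold and filled circles for those also past it with an estimated correlation. The immediate early genes reach a median of 1.18 under 5 µM digoxin at T20 and -1.31 from T0 to the T4 vehicle.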

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

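The test of shared vehicle arrays, the centring on poly-A controls, the levels against T16 by vehicle level and on the poly-A scale, and the estimated correlation without shared members were chosen only after the result was seen. The effect of digoxin differed between T20 and T4, by the test of the difference itself, for 67 genes at 5 µM and 1 gene at 0.5 µM. At 5 µM the differences of effects were 2.73 for LIF, 2.66 for IL1A, 2.58 for EDN1, 2.41 for CCN2, 2.26 for NR1D1 (-3.39 with its probe set of highest mean alone), 1.76 for IL1B, 1.54 for CCL2, 1.51 for BIRC3, 1.48 for FOS, 1.37 for GADD45A, 1.3 for EGR1, 1.06 for BCL6, 0.88 for MYC and 0.74 for HMGCS1. In the other direction they were -1.65 for ZNF480, -1.53 for RGCC, -1.41 for CCN4, -1.23 for CHAC1 and -1.22 for BAMBI. At 0.5 µM CCN4 differed by -1.07. The medians of the lists that differed were 0.58 for immediate early genes, 0.57 for NF-kB targets, 0.18 for sterol genes, -0.16 for ATF4 targets and -0.42 for histones at 5 µM, and 0.30 for immediate early genes and 0.26 for NF-kB targets at 0.5 µM.

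Other splits of the arrays were counted for each comparison of 2 groups. For the differences between times, the mean time and digoxin effects were set aside and the remainders were reassigned among the 12 arrays. For the 67 genes at 5 µM, 1 of 100 such reassignments, the real one, gave as many (highest other 2). This argues against chance assignment among these arrays. The reassignments take the arrays as independent, so they cannot exclude differences between cultures, which the labels do not give. For the 1 gene at 0.5 µM, 4 of 100 gave as many, and the highest other gave 6, more than the real count. The 10 comparisons of 3 arrays against 3 allow 10 splits each, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes. The real counts were 1148, 2594, 1267 and 3067 for digoxin 0.5 and 5 µM at T4 and then at T20 (highest other 0, 0, 0 and 3), 52 and 289 for the doses at T4 and T20 (0 and 0), and 3716, 2062, 2683 and 1656 for T16 against T0, T4 vehicle against T0, T20 vehicle against T16 and the vehicles (1, 1, 9 and 1).

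The first pattern is the more positive effect of 5 µM digoxin at T20 than at T4, by a median of 1.11 over the 47 genes higher in the difference. Of these, 15 rose at both times, 18 rose at T20 only, 10 fell at T4 only, 3 fell at T4 and rose at T20 and 1 fell at both. A common scale factor between the times was examined at the slope of 1.13. After the T4 effect was multiplied by it, 65 genes were called, 54 of them among the 67 called before. The slope was taken from these same data and changed the T4 effect only slightly. A similar count was therefore likely, and the test cannot decide on a common scale factor. A lower vehicle level at T20 is argued against by a median difference of 1.12 between T20 and T4 under digoxin itself, and of -0.07 in vehicle. The shift of the added control RNA may explain part of it: scaled to the poly-A controls, 13 of 47 genes were still called, as the median difference dropped from 1.11 to 0.66 and its SE grew from 0.19 to 0.25, with 47 of 47 above 0. A dependence on the time after synchronization stays open beside that shift, and so does the length of exposure, which is 4 h at both times by the sample labels but 20 h at T20 by the growth protocol. If the protocol holds, the 67 genes compare different exposures, and the 2 readings cannot be told apart in this design. The protocol lists T16 in the same way, although only untreated cells were collected then. This argues against counting its hours from digoxin or vehicle.

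The second pattern is that many genes lower in the T4 vehicle than at T0 were higher under digoxin, at 5 µM and T20 445 of 1052, while 45 were lower. The reverse was also seen. Of 1010 genes higher in the T4 vehicle than at T0, 85 were higher under 5 µM at T20. Genes that passed in opposite directions numbered 804 in all, the 445 included, and the correlations below cover both directions. At T4, where the vehicle arrays are shared, r was -0.48 against -0.5 in simulated unchanged groups, so r cannot tell the pattern from sharing. The covariance there, -0.0798, went beyond the -0.0206 simulated for shared arrays. Shared vehicle arrays are argued against as the whole cause by r = -0.36 across genes with the 5 µM effect at T20, which shares no array with the T4 vehicle and for which simulated groups gave 0. For the glucocorticoid list at 5 µM and T20 alone, members shared with other lists are argued against as the whole cause, since without its 7 shared members 6 of 11 genes rose and 2 fell (median 1.15; camera adjusted p of 0.000412, and 0.00963 with an estimated correlation). For the effect at T4, a slower loss of transcripts present at T0 was not tested and stays open for the genes that fell. It does not bear on genes that rose from T0 and were lower under digoxin. For the genes that fell from T0 and rose under 5 µM at T20, a slower loss of transcripts present at T16 stays open as well. Of 445 such genes 86.1% stood above their T16 mean under digoxin, above the bound set in advance, but 155 stood above it in the T20 vehicle too, and having been chosen for a rise over that vehicle they could not come out otherwise. Of the other 290 genes, 78.6% stood above T16, 126 past the threshold above it and 15 below, and on the scale of the poly-A controls 49% did, with 52 past the threshold above and 40 below.

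The third pattern is unequal change among the probe sets of a gene, called for 2068 of 9793 genes under 5 µM digoxin at T20. Dim probe sets are argued against as the whole cause, since 17.8% of genes were called with bright probe sets alone and 21.1% with all. A change of scale that depends on brightness may contribute: brighter probe sets had the higher change in 33.9% of these genes, below an even share.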

How the results depend on the processing

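Values as deposited, cyclic loess and poly-A centring were chosen only after the result was seen. Of 241 values of named genes, those that stayed on their side of the threshold were counted as kept. A change of direction counted against a value only if it passed in either fit. Kept were 233 as deposited, 237 with cyclic loess, array weights or eBayes with trend and robust, and 239 with arrays centred on their median gene value. With quantile normalization of gene values 236 were kept, with the replicate block 231, and with the mean of the probe sets or no filter 219. Poly-A centring kept 210, fits of only the groups compared 205, the probe set of highest mean 182, and the stricter filter 209 of 209. For counts that moved by over 1.5 times the cause was not tested, except that a minimum change lowers counts by construction. With the mean of the probe sets, 21 and 161 genes passed between doses at T4 and T20, and 0 and 32 for the difference between times at 0.5 and 5 µM (limma; 661 genes at an unadjusted p under 0.05 in the first of these with the main settings). With the probe set of highest mean, 422, 1126, 512 and 1829 genes passed for digoxin 0.5 and 5 µM at T4 and then T20, 1 and 117 between doses, 0 and 19 for the difference between times, and 1968, 821, 1023 and 583 for T16 against T0, T4 vehicle against T0, T20 vehicle against T16 and the vehicles. Lists called there were 3 for 0.5 µM at T4, 3 between doses at T20, 1 and 2 for the differences between times and 4 for T4 vehicle against T0. Reversed there were NR1D1 at T20 (-0.73 at 0.5 µM, -0.19 at 5 µM, and -3.39 for the difference between times at 5 µM) and EEF2K between doses at T4 (0.99). With no filter, 715 and 790 genes passed for 0.5 µM at T4 and T20, 7 and 139 between doses, 0 and 31 for the difference between times and 1038 between vehicles, with 9 and 10 lists for 0.5 and 5 µM at T4. Genes that rose and fell in both were then 329 and 309 for the doses at T4, 376 and 311 for the doses at T20 and 202 and 173 for the times at 0.5 µM.

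For the difference between times at 0.5 µM, 3 genes passed with the stricter filter, with quantile normalization of gene values, with arrays centred on their median gene value, with eBayes with trend and robust and with array weights, 2 with cyclic loess, and 0 with the replicate block, as deposited and with poly-A centring. Between doses at T4, 20 passed with the replicate block, 80 with trend and robust and 232 with array weights, which also gave 102 for the difference between times at 5 µM. Replicate numbers did not pair the arrays (4 of 30 pairs had a residual correlation over 0.1). In fits of only the groups compared, 720 and 546 genes passed for 0.5 µM at T4 and T20, 1982 for 5 µM at T20, 0 and 12 between doses, 31 for the difference between times at 5 µM, and 2298, 1107, 1511 and 815 for the comparisons of times. With poly-A centring, 594 and 2548 passed for 0.5 µM at T4 and T20, 9565 for 5 µM at T20, 15 and 5223 between doses, 480 for the difference at 5 µM, and 994, 5365 and 814 for T4 vehicle against T0, T20 vehicle against T16 and the vehicles. It reversed, at 5 µM and T20, ATP1B1 (-0.36), BMAL1 (-0.39), CIART (-0.16), CLOCK (-0.53), CRY2 (-0.21), CSNK1E (-0.28), NR1D2 (-0.16) and TEF (-0.28). With an estimated correlation, lists called were 1, 3 and 3 for 0.5 µM at T4, 5 µM at T4 and 0.5 µM at T20, 2 between doses at T4, 0 and 2 for the differences between times, and 9, 3, 4 and 8 for the comparisons of times. With a log2 change of at least 1 as well, 124, 303, 149 and 383 genes passed for digoxin, 7 and 34 between doses, 37 for the difference at 5 µM, and 482, 246, 243 and 149 for times.

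Leaving out 1 array gave 756 to 849 and 1905 to 2124 genes for 0.5 and 5 µM at T4, 876 to 907 and 2425 to 2729 at T20, 5 to 36 and 143 to 322 between doses at T4 and T20, 0 to 2 and 37 to 80 for the differences between times, and 2995 to 3564, 1487 to 1737, 1986 to 2620 and 1116 to 1296 for times. The T4 vehicle replicate 1 moved 0.5 µM at T4 (756), and at 5 µM the difference between times moved without it (42), without T4 5 µM replicates 1 and 3 (39 and 37) and without T20 5 µM replicate 1 (42). Between doses at T4 the count moved without T4 0.5 µM replicates 1, 2 and 3 (10, 5 and 16) and T4 5 µM replicates 1 and 3 (8 and 10), and at T20 without T20 0.5 µM replicates 1, 2 and 3 (177, 172 and 189) and T20 5 µM replicates 1 and 2 (143 and 185). At 0.5 µM the difference between times passed for 2 genes without T4 vehicle replicates 1 and 2 and for 0 without T4 0.5 µM replicates 2 and 3, each T20 vehicle array, and T20 0.5 µM replicates 2 and 3. The filter asked only that the highest group mean reach the limit of 6, so genes with other groups below it were tested, such as NR1D1 (4.76 in the T4 vehicle), and near the background or, for 13 genes, near the top of the scale differences can be compressed.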

Other observations

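Unequal change among the probe sets of a gene was also called for 324 genes at 0.5 µM and T4, 490 at 5 µM and T4 and 700 at 0.5 µM and T20. Between the times 90 genes were shared at 0.5 µM, against 23.2 for independent lists, and 251 at 5 µM, against 103.5. The genes named next were chosen after their values were seen. Under 5 µM at T4, the 19 probe sets of EIF5 ran from -3.74 to 1.07, the 21 of PER1 from -1.29 to 4.66 and the 55 of FN1 from -2.64 to 0.46, of which 12 stood near the top of the scale.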
